A study of Mus musculus with 6 samples.

How the data were processed

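RNA was measured in left ventricular tissue of C57BL/6J mice aged 12 months, in 3 libraries labelled wild-type (WT) and 3 labelled as overexpressing PGC-1α (group name PKI). Per the labels' protocols, RNA was isolated with Trizol from flash-frozen hearts, and libraries were built from 1 µg of total RNA with the Illumina TruSeq RNA kit, which does not mark strand, so reads of a gene and of an antisense neighbour cannot be told apart. The deposited values are FPKM, fragments scaled to transcript length and to the mapped total, with 1 value per gene and library, as the deposited table is named. Per the submitters' processing notes, CASAVA and Bowtie 0.12.2 were used and the genome build was mm9, with no role or order given. The program that made the FPKM values, its annotation and any filter are not given in the sources used here. The deposited table lists 52550 Ensembl gene identifiers, of which 52403 (99.72%) are also in GENCODE M21, the annotation of GRCm38, so the build behind the values is not settled. The table holds no coordinates. Positions printed here were looked up by identifier in GENCODE M21 (GRCm38) and were not converted to another build.

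Both deposited gene tables held identical values, and the table with symbols was used. A deposited summary of genes per FPKM interval was not used. FPKM are not counts, and the low values did not fall on whole multiples from which reads could be recovered, so the depth of each library is unknown and no counting interval is given. Transcripts of the mitochondrial genome and their near-identical nuclear copies (Gm29216, Gm10925, Gm28661, Gm28437, Gm28439, Gm28438 and Gm10222) were listed at similar high values. How reads were divided between them is unknown, and the values of mitochondrial genes are uncertain for that reason. The same holds for near-identical coding pairs: Hspa1a with Hspa1b, the alpha and the beta globins, Acta1 with Actc1 and Myh6 with Myh7.

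Groups were taken from the sample titles. Genes with a mean of at least 1 FPKM over the 6 libraries (9907 of 24705 above 0 in any library) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend, without a block, two-sided, and Benjamini-Hochberg adjustment over all tested genes. A gene was called changed at an adjusted p under 0.05, and every adjusted p below is from limma. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and fold values are ratios of mean FPKM. There were 91 symbols on more than 1 row, and tests ran per identifier. Ppargc1a was also compared by an exact permutation test of the 6 FPKM values.

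Before the data were examined, 40 gene lists (894 entries in all) were fixed, covering metabolism, mitochondria, contraction, matrix, stress responses and markers of other cell types. Each list with at least 5 tested genes (35 lists) was tested with camera from limma at its preset correlation of 0.01, which compares the list with all other genes, adjusted over the 35 lists. Camera with an estimated correlation and fry, which tests a list's own genes against no change, were run beside it. The genes named were also fixed by rule: Ppargc1a; the 12 genes with the smallest p in each direction among called genes without overlap between the groups and with a symbol other than a predicted-gene name; and the 3 members of each list with the smallest p. A few genes that meet the rule are not reported here. Other members of the lists that are named, such as Col1a1, Postn and Myl7, and the genes of the closing section outside the lists were chosen after their values were seen.

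Because FPKM are relative to each library's total, the gene tests and the list tests by preset camera and fry were also computed on scaled values. These were divided by median-of-ratios size factors, called "after scaling" below. Camera with an estimated correlation, the exact permutation test and the fits leaving out a library used values as deposited only. The other alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5 FPKM, quantile normalisation, no variance trend, array weights, a replicate block and leaving out each library in turn. Scaling to the FPKM total without mitochondrial genes and their nuclear copies was added after seeing the data.

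The fit was tested on simulated data for the comparison of PKI with WT, with 200 of 9907 genes changed. It recovered 35 of 70 genes changed 1.5-fold (50%), 48 of 72 changed 2-fold (66.7%) and 52 of 58 changed 4-fold (89.7%). Of 143 calls, 8 were unchanged genes. The simulated changes went in either direction at random, with no shift common to all genes. In the data 39.4% of tested genes were called, 92.5% of them higher. The simulated rates of recovery and of false calls therefore do not describe this comparison. No call was made among 40 simulated unchanged lists, and the changed list was called. The simulated genes varied independently, whereas the estimated correlation was 0.46 in the matrix list and 0.59 in the fibroblast list. The simulation therefore does not test camera calls of lists whose genes are correlated. A scaling factor of 1.2 put into the data was recovered as 1.2. This follows from how the size factors are computed and does not test whether scaling removes the displacement in the data correctly.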

Results

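Left ventricular RNA of 12-month-old C57BL/6J mice was sequenced in 6 libraries, 3 labelled wild-type (WT) and 3 labelled as overexpressing PGC-1α (group name PKI). PGC-1α, encoded by Ppargc1a, is a transcriptional coactivator of genes for mitochondrial biogenesis and oxidative metabolism. The design asks how the left ventricular transcriptome differs between mice labelled PKI and WT at this age. The labels number the samples within each group without stating that each came from a separate animal, so p-values measure only the spread between these samples, which may be technical. The depth of the libraries is unknown, as the values are FPKM. The FPKM of a library added up to between 708058 and 767757. Between 18672 and 19130 genes were above 0 in the WT libraries and between 19803 and 20202 in the libraries labelled PKI. Genes of the mitochondrial genome made up 57.8% ± 0.830 (SD, n = 3) of all FPKM in WT and 55.5% ± 0.146 (SD, n = 3) in libraries labelled PKI. Together with their near-identical nuclear copies they made up 81.8% to 82.3% in WT and 78.0% to 78.2% in libraries labelled PKI. Across genes, libraries of the same group correlated on the log scale at r of at least 0.982, and libraries of different groups at 0.974 or less.

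Ppargc1a (ENSMUSG00000029167, chromosome 5: 51454250 to 51567726, minus strand, GRCm38) was not higher in the libraries labelled PKI. Its level was 13.2 ± 0.942 FPKM (SD, n = 3) in WT, with library values of 14.2, 12.8 and 12.4, and 11.6 ± 0.176 (SD, n = 3) in libraries labelled PKI, with values of 11.6, 11.8 and 11.4. The log2 change was −0.16 (SE 0.07, 95% interval −0.327 to −0.000356), which did not pass the test over all genes (limma, adjusted p = 0.0967). Every library labelled PKI lay below every WT library, and the exact two-sided permutation test gave p = 0.1, the smallest value that the 20 arrangements of 3 against 3 allow. After scaling, the log2 change was −0.44 (SE 0.06, adjusted p = 0.00521). The deposited Ppargc1a values thus do not show the overexpression that the labels state, and all directions below are those of libraries labelled PKI against libraries labelled WT.

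**Figure D1:**
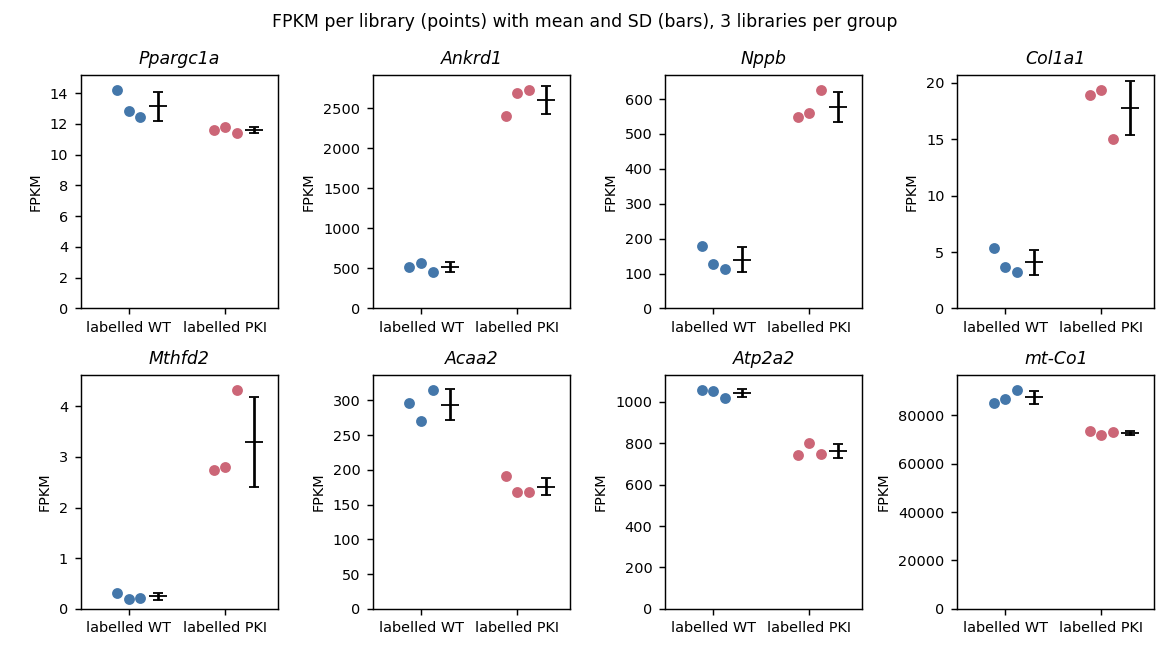
FPKM of 8 genes in each library (points), with the mean and SD of each group of 3 (bars); the vertical axes start at 0. Ppargc1a lies between 11.4 and 14.2 in all libraries, while Ankrd1 rises from a mean of 517 to 2606 and Acaa2 falls from 294 to 176.

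The left ventricles labelled PKI had higher levels of matrix, fibroblast, macrophage, fetal and stress genes and lower levels of genes of fatty acid oxidation and the mitochondrial genome. With an estimated correlation, the camera calls of the matrix, fibroblast, macrophage, fetal and stress, and fatty acid lists were lost (adjusted p = 0.303, 0.319, 0.319, 0.183 and 0.147). At an adjusted p under 0.05, 3902 of 9907 tested genes differed (39.4%), 3609 higher and 293 lower in libraries labelled PKI. Of these, 224 were higher and 10 lower by at least 1 on the log2 scale (114 and 30 after scaling). The whole distribution was displaced: the median log2 change over all tested genes was 0.21 (interquartile range 0.07 to 0.35). After scaling, with size factors of 0.898 to 0.922 in WT and 1.10 to 1.13 in libraries labelled PKI, the median was −0.02, and 1684 genes differed, 775 higher and 909 lower. The 775 were higher in both fits and 293 were lower in both, while 2834 were higher only as deposited and 616 lower only after scaling; 0 were called in opposite directions. The direction of a gene with a small rise can therefore depend on the scaling. Genes that fell as deposited also lay lower after it, which follows from the direction of the scaling. Counts after scaling stand beside each list. As deposited, values of all 3 libraries labelled PKI lay above all 3 WT values for 5087 tested genes (51.3%) and below for 449 (4.53%). Chance gives 10% for both together without a displacement. The displacement of the whole distribution raises the first share and lowers the second, so these shares largely restate it. They were not computed after scaling. Leaving out WT replicate 3 reduced the count to 2344 and leaving out PKI replicate 3 to 2498.

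**Figure D2:**
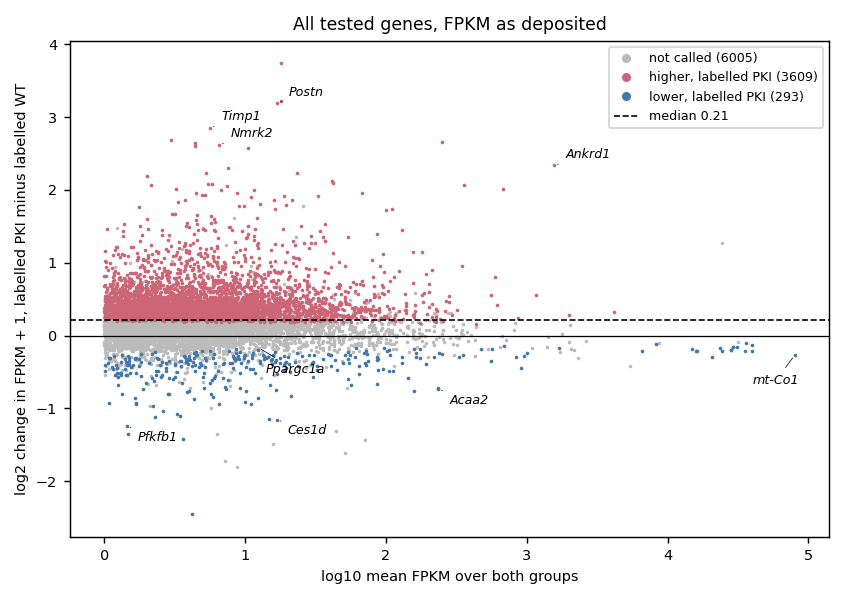
Log2 change of FPKM + 1 (vertical axis, labelled PKI minus labelled WT) against log10 mean FPKM (horizontal axis), 1 point per tested gene; 3609 genes called higher and 293 called lower are coloured. The dashed line marks the median of 0.21, and the protein-coding mitochondrial genes other than mt-Atp6 lie below 0.

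The gene with the smallest p was Nmrk2 (ENSMUSG00000004939, chromosome 10: 81198170 to 81202051), a nicotinamide riboside kinase of NAD synthesis, at 1.11 ± 0.127 FPKM in WT and 12.0 ± 0.916 in libraries labelled PKI (SD, n = 3 each), 10.8-fold higher (log2 2.62, SE 0.08, adjusted p = 5.87e-05). Ankrd1 (ENSMUSG00000024803, chromosome 19: 36111961 to 36120099), a stretch-responsive protein of the sarcomere, went from 517 ± 58.9 to 2606 ± 175 FPKM, 5.05-fold higher (adjusted p = 0.000131). Its relative Ankrd23 (ENSMUSG00000067653, chromosome 1: 36530188 to 36536883) was 2.77-fold higher (69.5 ± 3.50 and 192 ± 13.2). The other leading genes with adjusted p of 0.000301 fell into several kinds. Extracellular proteins were Mfap5 (6.23-fold), Svep1 (6.85-fold), Igfbp7 (3.35-fold) and the BMP antagonist Nbl1 (3.60-fold). The intermediate filament gene Des rose 1.94-fold from 236 ± 13.6 to 457 ± 4.99, the prion protein gene Prnp 1.96-fold, the small GTPase gene Rab31 2.88-fold and the glutathione peroxidase gene Gpx1 1.99-fold. All 12 genes selected by the rule were also higher after scaling, with log2 changes from 0.66 (Des, Prnp) to 2.40 (Nmrk2).

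Genes lower in libraries labelled PKI were led by Ces1d (ENSMUSG00000056973, chromosome 8: 93166068 to 93197838), a carboxylesterase that hydrolyses lipid esters, at 23.5 ± 1.82 FPKM in WT and 10.01 ± 0.550 in libraries labelled PKI (2.35-fold lower, log2 −1.15, SE 0.08, adjusted p = 0.000424). The splicing factor gene Rbfox1 (ENSMUSG00000008658, chromosome 16: 5885355 to 7411526) was 1.94-fold lower (7.60 ± 0.0321 and 3.92 ± 0.222), and Kcnj5 (ENSMUSG00000032034, chromosome 9: 32314707 to 32344350), a subunit of the acetylcholine-gated potassium channel, was 2.01-fold lower (13.3 ± 0.709 and 6.59 ± 0.573). Metabolic enzymes among the 12 were Bckdhb of branched-chain amino acid breakdown (1.65-fold lower), the fatty acid oxidation enzymes Ech1 (1.66-fold) and Acaa2 (1.67-fold, 294 ± 22.3 and 176 ± 12.9) and the monoamine oxidase gene Maob (1.91-fold). Atp2a2, which encodes the calcium pump of the sarcoplasmic reticulum, fell from 1043 ± 21.3 to 763 ± 33.5 FPKM (log2 −0.45, adjusted p = 0.00125). The adhesion gene Ctnna3 was 2.93-fold lower, the phosphatase subunit gene Ppp2r3a 1.74-fold, the ephrin gene Efnb3 2.33-fold and the secreted protein gene Retnla 3.82-fold. All 12 remained called after scaling, with log2 changes from −0.75 (Atp2a2) to −1.63 (Retnla). Scaling lowered the values of libraries labelled PKI against WT, so genes already lower could not turn, and this outcome lends them no support.

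Of the 35 lists tested with camera, 8 were called higher and 11 lower relative to all other genes. With an estimated correlation 1 call held, that of the mitochondrially encoded genes. Fry called 24 lists higher and 5 lower. After scaling, camera called 8 lists higher and 12 lower, and fry 11 higher and 18 lower. Without a filter on low values, camera also called higher the lists on antioxidants (adjusted p = 9.72e-05), endoplasmic reticulum stress (0.000654), interferon (0.00115), senescence (0.000850) and the proteasome (0.00639). With quantile normalisation it called antioxidants (0.0369), endoplasmic reticulum stress (0.0374), interferon (0.00859) and senescence (0.0491) higher.

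Matrix genes rose together. Of 35 tested genes of extracellular matrix and fibrosis, 32 rose and 0 fell (33 adjusted over the list alone, 31 after scaling), with a median log2 change of 1.35, 1.08 after scaling (camera adjusted p = 2.00e-12; adjusted p = 0.303 with an estimated correlation). Col1a1, the main chain of fibrillar collagen, rose from 4.09 ± 1.12 to 17.8 ± 2.38 FPKM, and the collagen-binding proteoglycan gene Bgn rose 4.43-fold. Col6a1 rose 2.85-fold, and Timp1, an inhibitor of matrix metalloproteinases, rose from 0.624 ± 0.389 to 10.6 ± 2.15. Postn, a matrix protein of activated fibroblasts, rose from 2.42 ± 0.884 to 31.4 ± 13.9. Tgfb1, Mmp3 and Fmod did not pass (log2 0.32, 0.28 and 0.64).

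Fibroblast markers moved with the matrix genes: 11 of 14 rose and 0 fell (12 adjusted over the list alone, 10 after scaling), with a median of 0.98 (camera adjusted p = 9.21e-05; adjusted p = 0.319 with an estimated correlation). Besides Mfap5, Pcolce rose 3.29-fold and Col14a1 5.27-fold. Pdgfra, Gsn and Scara5 did not pass (log2 0.42, 0.31 and 0.26). Macrophage markers rose in 11 of 12 tested members (11 adjusted over the list alone, 9 after scaling), with a median of 1.01 (camera adjusted p = 0.000176; adjusted p = 0.319 with an estimated correlation). The complement genes C1qa and C1qc rose 2.51-fold and 2.34-fold, Cd68 2.80-fold and Lyz2 from 47.6 ± 13.4 to 124 ± 8.58, while Cd163 was at log2 0.15 and turned after scaling (−0.01). Of 15 endothelial markers, 4 rose (3 adjusted over the list alone, 0 after scaling), among them Ly6c1 (1.27-fold), Plvap (1.61-fold) and Pecam1 (1.19-fold, whose direction turns after scaling, log2 −0.04). Their median was 0.23, close to that of all genes, and −0.04 after scaling (camera adjusted p = 0.798). Of 12 smooth muscle and pericyte markers, 4 rose (also 4 adjusted over the list alone), namely Acta2 (2.20-fold), Tagln, Rgs5 and Notch3. After scaling 1 was higher, Acta2, and 2 were lower. Camera was directed down, with the median at 0.30 (camera adjusted p = 0.981). Red blood cell markers fell in 5 of 6 tested members (5 adjusted over the list alone, 5 after scaling), with a median of −0.47 (camera adjusted p = 2.96e-07; adjusted p = 0.103 with an estimated correlation). The beta globin genes Hbb-bs and Hbb-bt were 1.72-fold and 1.62-fold lower, and Alas2, the first enzyme of erythroid haem synthesis, 1.48-fold lower.

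**Figure D3:**
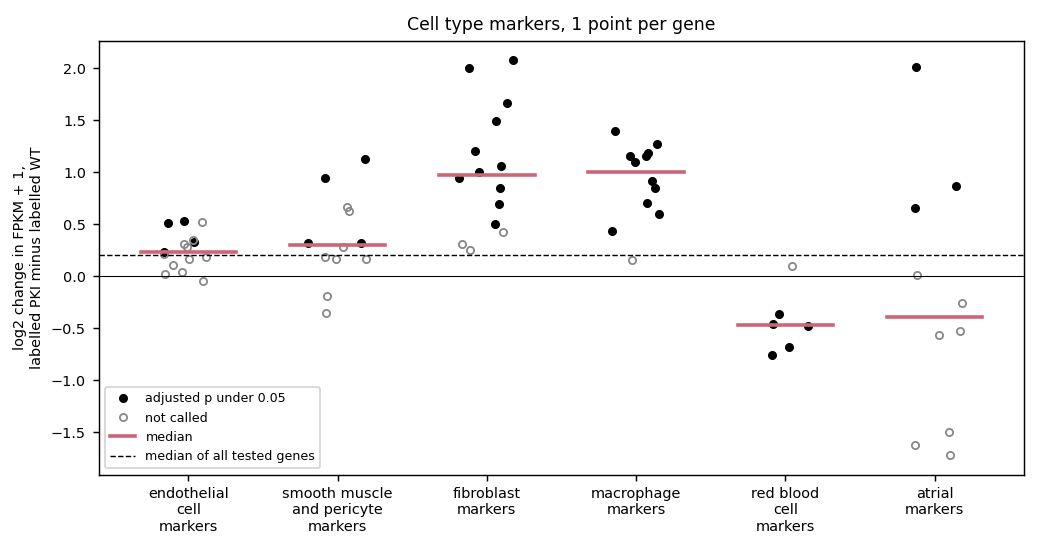
Log2 change of FPKM + 1 (vertical axis, labelled PKI minus labelled WT) of cell type markers, 1 point per gene, filled where the adjusted p is under 0.05, with the list's median (red bar) and the median of all tested genes (dashed, 0.21). Fibroblast and macrophage markers have medians of 0.98 and 1.01, endothelial markers 0.23 (−0.04 after scaling) and red blood cell markers −0.47.

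Among 10 tested atrial markers, 3 rose and 0 fell (3 adjusted over the list alone; 3 higher and 1 lower after scaling): Clu (1.84-fold), Pam (1.59-fold) and Nppa, which ventricles also express under load. Camera called the list lower (adjusted p = 0.0185; adjusted p = 0.333 with an estimated correlation; 0.789 after scaling), with a median of −0.39, while fry was directed up (adjusted p = 0.240). Myl7, the atrial myosin light chain, differed widely between libraries, at 74.3, 40.5 and 91.3 FPKM in WT and 6.61, 14.8 and 81.9 in libraries labelled PKI, and did not pass (adjusted p = 0.144). The atrial call was lost without WT replicate 3 (adjusted p = 0.0882), PKI replicate 1 (0.0972) or PKI replicate 2 (0.0670), without a filter on low values (0.0736), at a minimum mean of 5 FPKM (0.180), with quantile normalisation (0.849) and when scaled to the nuclear total (0.360). Of 5 tested adipocyte markers, 1 rose, Cidea (1.56-fold; also 1 adjusted over the list alone and 1 after scaling), with Cfd and Car3 at log2 1.00 and 0.56 (camera adjusted p = 0.694). Of 2 tested skeletal muscle markers, Mybpc2 rose from 1.46 ± 0.251 to 8.50 ± 1.89 FPKM (also adjusted over the list alone and after scaling), and Ckm, which the heart expresses strongly, was at log2 −0.13 and fell after scaling (log2 −0.43). Of the lymphocyte and neutrophil, neuron and Schwann cell, and epicardial and mesothelial markers, 0 reached the level for testing. The Y-linked genes Ddx3y, Eif2s3y and Uty were expressed in all 6 libraries, with Xist at 0.0196 FPKM or less; 0 of the 3 were called, also adjusted over the list alone and after scaling, and their log2 changes of 0.03, 0.22 and 0.13 turned to −0.23, −0.04 and −0.04 after scaling.

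Genes of the fetal and stress programme of the heart rose in 11 of 13 tested members (11 adjusted over the list alone, 9 after scaling), with a median log2 change of 1.60, 1.43 after scaling (camera adjusted p = 9.21e-05; adjusted p = 0.183 with an estimated correlation). The natriuretic peptide genes Nppb and Nppa rose from 140 ± 35.6 to 578 ± 42.4 FPKM and from 261 ± 69.0 to 1088 ± 413. Xirp2, an actin-binding protein of the intercalated disc, rose 3.997-fold, Acta1, the skeletal actin gene, 6.13-fold, and Myh7, the slow myosin heavy chain, 2.24-fold. Immediate early genes rose in 15 of 18 members (16 adjusted over the list alone, 11 after scaling), with a median of 0.93 (camera adjusted p = 0.000408; adjusted p = 0.319 with an estimated correlation). Ier3 rose 2.40-fold, Fosl2 2.82-fold and Egr1 3.10-fold. Heat shock and chaperone genes rose in 14 of 19 members (14 adjusted over the list alone; 9 higher and 1 lower after scaling), with a median of 0.58 (camera adjusted p = 0.000821; adjusted p = 0.319 with an estimated correlation). The cardiac small heat shock protein genes Hspb7 and Hspb8 rose from 431 ± 11.0 to 753 ± 38.6 and from 148 ± 3.23 to 222 ± 3.24 FPKM, and Hspa1b, which shares reads with Hspa1a, from 0.438 ± 0.0684 to 8.39 ± 3.28.

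Inflammation genes rose in 13 of 16 tested members (13 adjusted over the list alone, 7 after scaling), with a median of 0.56 (camera adjusted p = 0.0296; adjusted p = 0.319 with an estimated correlation; lost without WT replicate 3, at 0.0769). Complement C4b rose 4.36-fold, the chemokine gene Ccl9 2.15-fold and the adhesion gene Icam1 1.77-fold, beside the macrophage markers above. Of 17 interferon response genes, 10 rose (11 adjusted over the list alone, 4 after scaling), led by Ifi27l2a (2.72-fold), Irf1 (1.67-fold) and Irf9 (1.73-fold). Irf1 did not pass after scaling (adjusted p = 0.0539). The interferon list was not called as deposited (camera adjusted p = 0.173) and was called higher after scaling (0.00598) and without WT replicate 1 (0.0147). Of 15 genes of senescence, cell cycle and DNA damage, 8 rose (10 adjusted over the list alone; 4 higher and 1 lower after scaling), with the cell cycle inhibitor gene Cdkn1a at 1.89 ± 0.440 and 7.27 ± 0.440 FPKM and Ccnd2 1.69-fold higher (camera adjusted p = 0.229). Of 17 genes of endoplasmic reticulum stress and the integrated stress response, 9 rose (9 adjusted over the list alone; 6 higher and 1 lower after scaling), and the list was not called (camera adjusted p = 0.173; median 0.26, −0.03 after scaling). The members that rose included Mthfd2, an enzyme of mitochondrial folate metabolism (0.243 ± 0.0674 and 3.29 ± 0.893 FPKM), Aldh18a1 of proline synthesis (2.01-fold) and the transcription factor gene Atf4 (1.72-fold), while the chaperone gene Hspa5 was at log2 −0.06. Of 27 antioxidant genes, 15 rose (15 adjusted over the list alone; 5 higher and 1 lower after scaling), and the list did not pass (camera adjusted p = 0.0602; 0.0223 without WT replicate 3 and 0.0293 without PKI replicate 1). Besides Gpx1, the metallothionein gene Mt2 rose 3.99-fold and the haem oxygenase gene Hmox1 2.15-fold.

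Fatty acid uptake and oxidation moved the other way. Of 31 tested genes, 17 fell and 1 rose (also 17 and 1 adjusted over the list alone; 26 lower and 0 higher after scaling), with a median of −0.24, −0.52 after scaling (camera adjusted p = 6.99e-24; adjusted p = 0.147 with an estimated correlation). Acaa2, the last thiolase step of the pathway, was 1.67-fold lower, Acadm, the medium-chain dehydrogenase, fell from 218 ± 7.20 to 165 ± 4.45 FPKM, and Ucp3 was 1.95-fold lower. Ucp2 rose 1.72-fold and did not pass after scaling (adjusted p = 0.222). Of 16 genes of ketone and branched-chain amino acid catabolism, 6 fell and 2 rose (also 6 and 2 adjusted over the list alone; 9 and 1 after scaling), with a median of −0.21 (camera adjusted p = 1.38e-08; adjusted p = 0.0623 with an estimated correlation). Bckdhb and Dbt, subunits of the branched-chain ketoacid dehydrogenase, were 1.65-fold and 1.25-fold lower, whereas Bdh1, the mitochondrial enzyme of ketone oxidation, rose from 12.3 ± 1.29 to 31.5 ± 1.82 FPKM and remained higher after scaling (log2 1.01, adjusted p = 0.00122). Of 26 genes of the tricarboxylic acid cycle and pyruvate oxidation, 4 fell and 1 rose (1 and 0 adjusted over the list alone; 16 lower and 0 higher after scaling), with a median of −0.05 (camera adjusted p = 1.12e-07; adjusted p = 0.0623 with an estimated correlation). Pdk2 and Idh2 were 1.28-fold and 1.23-fold lower, and Pdhx was 1.18-fold higher and turned after scaling (log2 −0.06).

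Of 13 mitochondrially encoded genes, 11 fell and 0 rose (12 lower and 1 higher adjusted over the list alone; 12 lower after scaling), with a median of −0.16, −0.46 after scaling (camera adjusted p = 1.94e-17; adjusted p = 0.0462 with an estimated correlation). This call was lost with quantile normalisation (adjusted p = 0.448). That method gives every library the same value at each rank. A joint fall of genes among the highest of every library, as these are, is therefore largely removed whether or not it is real. The member higher over the list alone was mt-Atp6, at 8216 and 7966 FPKM in WT replicates 2 and 3 against 30710 to 34450 in the other 4 libraries, WT replicate 1 among them. mt-Co1, a catalytic subunit of cytochrome oxidase, was 1.202-fold lower, mt-Nd1 1.16-fold and mt-Nd5 1.22-fold. These values are uncertain because of nuclear copies. Of 37 complex I genes, 2 rose and 1 fell (0 adjusted over the list alone; 0 higher and 15 lower after scaling): Ndufb3 and Ndufb6 were 1.19-fold and 1.22-fold higher and turned after scaling (log2 −0.05 and −0.01), and Ndufs1 was 1.17-fold lower. Of 27 genes of complexes II to IV, 4 rose and 3 fell (3 and 3 adjusted over the list alone; 0 and 12 after scaling), with Sdha 1.23-fold lower and Cox8a and Cox6a1 1.45-fold and 1.54-fold higher. Of 17 ATP synthase genes, 1 rose and 2 fell (also 1 and 2 adjusted over the list alone; 0 and 8 after scaling), with Atp5b 1.14-fold and Atp5a1 1.10-fold lower and the inhibitor gene Atpif1 1.30-fold higher. The medians of these 3 lists were 0.06, 0.00 and 0.01, above 0 yet under that of all genes, and camera called them lower (adjusted p = 0.00327, 0.000620 and 0.000555; with an estimated correlation adjusted p = 0.404, 0.319 and 0.147). Their medians after scaling were −0.24, −0.29 and −0.29. The complex I call was lost without PKI replicate 2 (adjusted p = 0.0948) and without a filter on low values (0.324).

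Among 24 regulators of the PGC-1α family and their partners, 2 rose and 4 fell (2 and 3 adjusted over the list alone; 1 and 7 after scaling). Nfe2l2, the regulator of antioxidant genes, was 1.47-fold higher (adjusted p = 0.0449 after scaling). The deacetylase gene Sirt1 was 1.42-fold higher as deposited but did not pass after scaling (adjusted p = 0.251). Perm1, a muscle regulator induced by PGC-1α, was 1.203-fold lower and the fatty acid receptor gene Ppara 1.37-fold lower. Camera called the list lower (adjusted p = 0.000902; adjusted p = 0.196 with an estimated correlation), with a median and mean of 0.06 each and a median of −0.17 after scaling. Of 11 genes of mitochondrial DNA maintenance and transcription, Lonp1 rose (1.43-fold) and Tfb1m fell (1.29-fold), also adjusted over the list alone, and Ssbp1 did not pass (log2 0.24); after scaling 1 was higher and 3 lower (camera adjusted p = 0.206). The mitochondrial transcription factor gene Tfam was at log2 −0.06. Of 75 genes of the mitochondrial ribosome, 9 rose (5 adjusted over the list alone; 1 higher and 11 lower after scaling), led by Mrpl20 (1.60-fold), Mrpl52 (1.41-fold) and Mrpl33 (1.43-fold). Among the named genes only Mrpl20 was called higher after scaling. The mitochondrial ribosome list was not called as deposited (camera adjusted p = 0.229) and was called lower after scaling (9.37e-05). Of 21 genes of mitochondrial dynamics and mitophagy, 7 rose and 2 fell (camera adjusted p = 0.550). The counts were also 7 and 2 adjusted over the list alone, and 1 and 3 after scaling. The autophagy receptor gene Sqstm1 was 1.62-fold and Gabarapl1 1.37-fold higher, and the mitophagy kinase gene Pink1 was 1.41-fold lower. Gabarapl1 did not pass after scaling (adjusted p = 0.178).

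Glucose uptake and glycolysis genes went both ways, with 12 of 24 higher and 3 lower (14 and 4 adjusted over the list alone; 2 and 10 after scaling) and no call of the list (camera adjusted p = 0.222; median 0.18, −0.12 after scaling). Pfkp, the platelet-type phosphofructokinase, rose 2.82-fold and Pgam1 2.09-fold, both also after scaling, and Pfkfb1 fell from 2.44 ± 0.593 to 0.449 ± 0.218 FPKM. Of 16 genes of lipid synthesis and cholesterol, 4 rose and 1 fell (also 4 and 1 adjusted over the list alone; 0 and 5 after scaling), with Fasn 1.70-fold and Idi1 1.59-fold higher and Dgat2 1.25-fold lower (camera adjusted p = 0.0913; 0.0449 at a minimum mean of 5 FPKM, 0.0450 without WT replicate 2 and 0.0479 without PKI replicate 3).

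Of 22 sarcomere genes, 9 rose and 3 fell (also 9 and 3 adjusted over the list alone; 2 and 10 after scaling). Besides Des, Tnnc1, the cardiac troponin C gene, rose from 943 ± 3.58 to 1395 ± 20.6 FPKM. Mybpc3 rose 1.33-fold as deposited but did not pass after scaling (adjusted p = 0.218). Tnni3, Pln and Myl2 were 1.21-fold, 1.18-fold and 1.13-fold lower. The list was not called as deposited (camera adjusted p = 0.190; median 0.11) and was called lower after scaling (0.00636; median −0.18) and when scaled to the nuclear total (0.0147), but not with quantile normalisation (0.972). Of 24 genes of calcium handling and ion channels, 3 rose and 3 fell (also 3 and 3 adjusted over the list alone; 0 and 9 after scaling), with a median of −0.01 (camera called lower, adjusted p = 5.15e-05; adjusted p = 0.103 with an estimated correlation). Besides Atp2a2, Kcnd2, a channel of the transient outward potassium current, was 2.14-fold lower and Kcnj3, the partner of Kcnj5, 1.72-fold lower, and the calcium-binding calsequestrin gene Casq2 was 1.36-fold higher as deposited but did not pass after scaling (adjusted p = 0.0974).

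**Figure D4:**
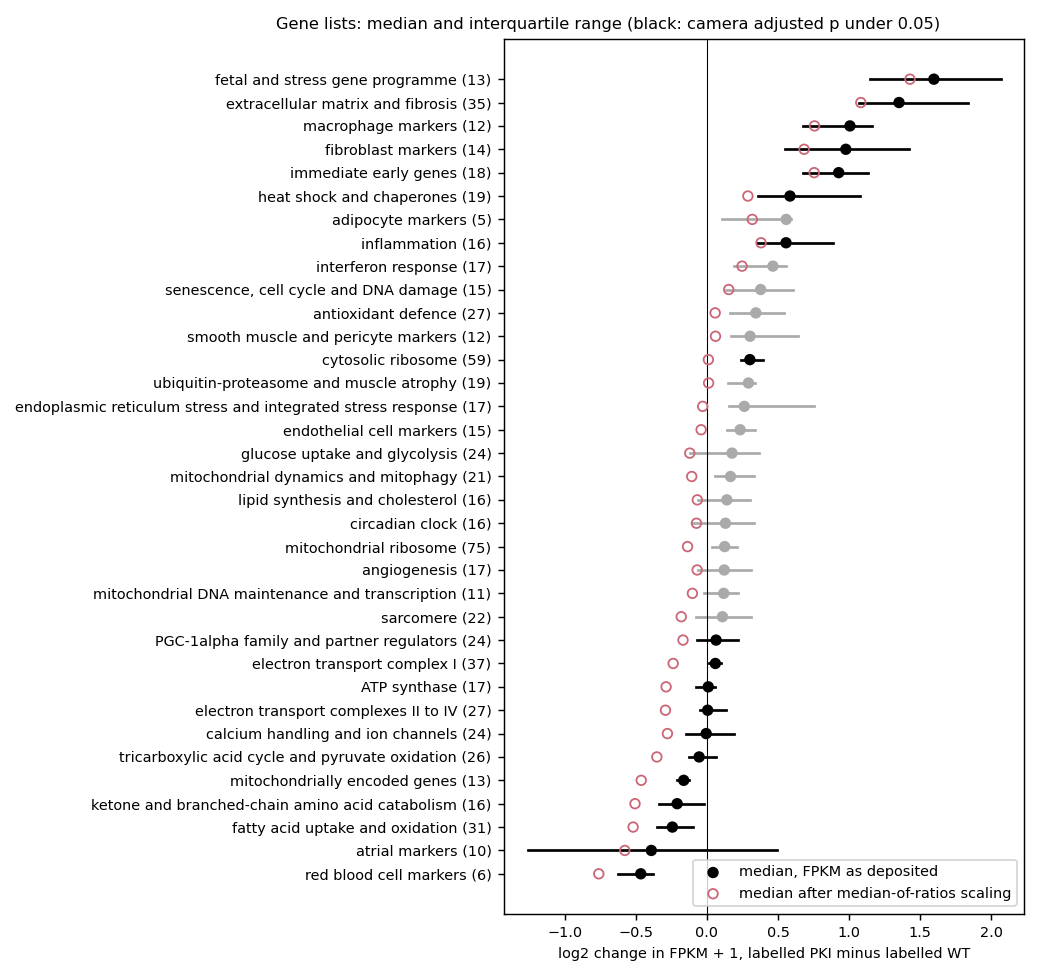
Median (points) and interquartile range (lines) of the log2 change of FPKM + 1 (horizontal axis) in each of 35 gene lists, with the number of tested genes in brackets; black marks lists with a camera adjusted p under 0.05, and open circles are medians after scaling. The fetal and stress programme (1.60) and the extracellular matrix (1.35) lie highest, and 14 lists with a median above 0 as deposited lie below 0 after scaling.

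Cytosolic ribosome genes rose in 43 of 59 members (49 adjusted over the list alone), but after scaling 2 were higher and 1 lower. Camera called the list higher as deposited (adjusted p = 6.67e-05; adjusted p = 0.147 with an estimated correlation) and not after scaling (0.295), where the median went from 0.30 to 0.01. It was called higher with quantile normalisation (0.000117) and when scaled to the nuclear total (0.0206). Rpl3 (1.94-fold) was higher in both fits, and Rpl19 (1.37-fold) only as deposited. Of 19 genes of the ubiquitin-proteasome system and muscle atrophy, 11 rose and 1 fell (14 and 1 adjusted over the list alone; 0 and 1 after scaling), among them the proteasome subunit genes Psmc1 (1.38-fold) and Psmc4 (1.30-fold) and the ligase gene Fbxo30 (1.67-fold); the atrophy ligases Fbxo32 and Trim63 were at log2 0.09 and 0.04 and turned after scaling, to −0.19 and −0.25 (camera adjusted p = 0.195). Of 17 angiogenesis genes, 7 rose and 2 fell (also 7 and 2 adjusted over the list alone; 0 and 5 after scaling), with Hif1a 1.52-fold and Nrp1 1.36-fold higher and Apln 1.75-fold lower (camera adjusted p = 0.173). Of 16 clock genes, 2 rose (also 2 adjusted over the list alone), the repressor genes Bhlhe40 (1.71-fold) and Bhlhe41 (1.30-fold). After scaling 1 was higher, Bhlhe40, and 4 were lower. Nfil3 did not pass at log2 0.37 (camera adjusted p of the list = 0.104). For the lists on glycolysis, lipid synthesis, sarcomere, angiogenesis, clock, mitochondrial ribosome, DNA maintenance and mitophagy, camera was directed down while the median lay above 0.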

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

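Scaling to the total of nuclear genes was chosen only after the results were seen. The 24 leading genes kept their direction and their call in all alternatives in which they were tested, 18 of 18 at a minimum mean of 5 FPKM, with adjusted p of 0.00892 or less. They were selected for small p and no overlap in these same libraries, which makes such an outcome likely. The count of 3902 changed genes (3609 higher, 293 lower) became 1684 (775, 909) with median-of-ratios size factors, 1515 (753, 762) with quantile normalisation and 1622 (1019, 603) when scaled to the total of nuclear genes; each brings the median change of all genes nearer to 0. A minimum mean of 5 FPKM left fewer genes to test and 1925 changed (1739, 186). Leaving out 1 library gave 2344 to 3425 changed genes, 2179 to 3162 higher and 165 to 263 lower, with fewer samples per fit; the shifts beyond 1.5-fold were those without WT replicate 3 (2344, 2179, 165) and without PKI replicate 3 (2498, 2325, 173). Other pseudocounts, no filter (2977), no variance trend and array weights (4421) stayed within 1.5-fold. Ppargc1a passed the threshold on the lower side with median-of-ratios size factors (−0.44, adjusted p = 0.00521, range over all alternatives to 0.218), quantile normalisation (−0.42, 0.0081) and the nuclear total (−0.36, 0.0161), the same alternatives. Of 35 lists, camera called 19 (8 higher, 11 lower), camera with an estimated correlation 1 (0 higher, 1 lower), and fry, which asks another question, 29 (24 higher, 5 lower); without a filter on low values 13 lists were higher, and the cause was not tested. Signs reversed, without a call in the new direction, for Ndufb3 (−0.0484), Ndufb6 (−0.0064), Pdhx (−0.0634), Pecam1 (−0.0438), Uty (−0.0364), Eif2s3y (−0.0428) and Ddx3y (−0.231) with median-of-ratios size factors, for Pdhx (−0.0205), Pecam1 (−0.0337), Uty (−0.0667), Eif2s3y (−0.0299) and Ddx3y (−0.208) with quantile normalisation, and for Ddx3y when scaled to the nuclear total (−0.155) and without PKI replicate 3 (−0.0379; 0.0791 without PKI replicate 1). Of 126 named genes, besides those reversed, 23 lost their call with median-of-ratios size factors, 26 with quantile normalisation, 21 with the nuclear total, 13 without a filter and between 4 and 15 when 1 library was left out. Over all tested genes, equal replicate numbers showed no pairing. Deviations of same-numbered libraries correlated at −0.104, 0.00115 and 0.0529, and not every library correlated best with its own number. These correlations cannot exclude a shared preparation of same-numbered samples. Some mitochondrial tRNA genes were low in both replicate 2 libraries, among them mt-Tk (23.7 FPKM in WT and 44.0 in PKI, against 79.2 to 106 in the others), while mt-Th and mt-Tc did not follow this pattern. With the replicate number as a block 2849 genes changed (2625 higher, 224 lower), 2755 of them shared, 19 lists were called and 9 named genes lost their call. Depth is unknown, so the precision of low values cannot be given.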

Other observations

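The tests on the excess of higher genes, on Ppargc1a and on fibroblast and macrophage markers, and the families and genes named here, were chosen only after these results were seen; the splits of the libraries were not, and the bounds for the excess were set before its test values were computed.

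Families sharing a symbol stem were also scanned (150 families with at least 8 tested genes), and camera called 2 higher and 5 lower (0 with an estimated correlation). Genes of the fixed lists were not removed. The Col, Rpl and Ndufs families share genes with the matrix, cytosolic ribosome and complex I lists, so their calls are not separate from those lists. Of 18 genes with the stem Col, 17 rose, 16 of them also after scaling (adjusted p = 1.40e-06; adjusted p = 0.959 with an estimated correlation). The exception, Col4a3bp, encodes a ceramide transporter and is no collagen. Among 12 Asb genes, substrate receptors of ubiquitin ligases, 3 fell, 5 after scaling (adjusted p = 0.000522; adjusted p = 0.778 with an estimated correlation): Asb14 was 1.47-fold, Asb15 1.42-fold and Asb10 1.22-fold lower. Among 12 Aldh genes 4 rose and 5 fell, 3 and 5 after scaling, and the family was called lower (adjusted p = 0.0419; adjusted p = 0.778 with an estimated correlation). The retinoic acid synthesis genes Aldh1a1 and Aldh1a2 rose (log2 0.76 and 1.11) while Aldh2 and Aldh6a1 fell (−0.27 and −0.38). The annexins did not pass as a family (adjusted p = 0.0662; adjusted p = 0.959 with an estimated correlation), though 7 of 8 rose, 5 after scaling, with Anxa1 2.74-fold and Anxa2 2.27-fold higher. The other families called were Rpl (higher, 40 of 49 members and 1 lower, 1 and 1 after scaling; adjusted p = 0.00250), Mir (lower, 0 of 11 members called, 1 lower after scaling; adjusted p = 0.0127), Ndufs (lower, 1 of 8, 6 after scaling; 0.0419) and Pex (lower, 0 of 13, 4 after scaling; 0.0419), each with adjusted p = 0.778 with an estimated correlation.

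The matrix protein gene Cilp had the largest positive log2 change of all tested genes, as deposited and after scaling, from 1.69 ± 1.10 to 34.55 ± 12.8 FPKM (SD, n = 3; log2 3.74, adjusted p = 0.000726), followed by the acute-phase protease inhibitor gene Serpina3n, from 2.71 ± 1.10 to 33.3 ± 9.08 (log2 3.22, adjusted p = 0.000591). The fibroblast transcription factor gene Meox1 rose 3.84-fold (adjusted p = 0.000301). The orphan receptor gene Gpr22 and the oxoglutarate dehydrogenase-like gene Ogdhl were 1.98-fold and 1.82-fold lower (adjusted p = 0.00507 and 0.00254). Cilp, Serpina3n, Meox1, Gpr22 and Ogdhl were also called after scaling.

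The excess of genes higher than lower in libraries labelled PKI (3609 against 293) was weighed against 3 technical explanations. Gene length bias is argued against, since the lowest median log2 ratio of mean FPKM among 3 tertiles of exonic length was 0.270, close to that of all genes (0.272). For a single factor between the groups, the medians by quartile of expression were 0.32, 0.29, 0.26 and 0.23. They span 0.0937, narrowly within the 0.1 set before that value was computed, and so meet that prediction. The medians nevertheless fell steadily from the lowest to the highest quartile. The mitochondrially encoded genes, among the highest, went the other way (median log2 change −0.16), so such a factor cannot hold for all genes. Mitochondrial transcripts and their nuclear copies may supply much of that factor, as scaling to the total of the other genes lowered the median ratio from 0.272 to 0.0588, but this lies between the bounds of 0.05 and 0.1, so whether they account for all of it stays open. Whether that larger mitochondrial share in WT is itself biological was not tested; of the 10 splits of the 6 libraries, the real split alone (1) gave 3902 changed genes and the highest other gave 2, and 10 splits are too few for a share under 0.05.

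Ppargc1a was not higher in libraries labelled PKI. An exchange of 1 library between the groups is argued against, since the lowest correlation within a group exceeded the highest between groups by 0.00782. A reversal of all 6 labels cannot be told apart from the labels as given by the log2 change of −0.16, because no source used here states the excess that the construct gives. Construct reads that were not assigned to the Ppargc1a gene model could leave the same −0.16, and the table lists Ensembl genes only. An overexpression that had ended, or had lowered the endogenous transcript, by 12 months is a biological possibility that was not tested.

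All 14 fibroblast markers and 12 of 16 macrophage markers were high enough to test. Of these, 11 fibroblast and 11 macrophage markers were higher in libraries labelled PKI (10 and 9 after scaling). Both list calls were lost with an estimated correlation (camera adjusted p = 0.319 each). No marker of either stands in another list. The most abundant were Gsn (199 ± 43.7 and 243 ± 5.84 FPKM), which did not pass, Dcn (61.4 ± 9.06 and 119 ± 14.3) and Lyz2 (47.6 ± 13.4 and 124 ± 8.58). A lower cardiomyocyte share alone is argued against, because fibroblast markers exceeded endothelial markers by 0.744 in the median (permutation p = 3e-05 over genes, which are not independent replicates) and macrophage markers by 0.773 (permutation p = 3e-04). Atrial tissue carried over is argued against by Myl7, Myl4 and Sln, whose median log2 change was −1.62 (SE 0.81, 0.68 and 0.65), and PKI replicate 1 had Nppa at 654 FPKM with Myl7 at 6.61, while WT had Nppa at 339 or less with Myl7 at 40.5 or more. The fibroblast markers rose by unequal amounts, also as ratios of mean FPKM (Mfap5 6.23-fold, Pcolce 3.29-fold). The quartiles of their log2 changes were 0.55 and 1.42, and SE were 0.11 for Mfap5, 0.12 for Pcolce and 0.15 for Col14a1. Such unequal rises would argue against more fibroblasts with unchanged expression per cell as the only cause if every marker were made only by fibroblasts. Whether each marker is made only by fibroblasts was not tested. The interquartile range of 0.870 lies between the bounds, which were set after the results were seen, so it decides neither way. How far cell number and expression per cell each contribute therefore cannot be told apart. Macrophage markers were not tested in this way. A biological difference between the groups by genotype label also stays open and was not tested.

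PKI replicate 2 had Alb at 34.7 and Apoa1 at 17.7 FPKM, plasma protein genes of the liver, against at most 1.99 and 0.824 in the other 5 libraries; without this library 2989 genes changed. The same library had Mb, the myoglobin gene, at 2753 FPKM against 5613 to 6211 elsewhere. WT replicates 2 and 3 had mt-Atp6 at 8216 and 7966 FPKM against 30710 to 34450 in the other 4 libraries. WT replicate 2 and PKI replicate 2 had mt-Td at 77.6 and 106 FPKM against 203 to 258 in the others. The tRNA genes mt-Tk, mt-Tr and mt-Tv were also lowest in these libraries, while mt-Th and mt-Tc were not. The epithelial keratin gene Krt18, below the level for testing, was at 0.0988, 0.0357 and 0.119 FPKM in WT and 1.09, 2.96 and 0.793 in libraries labelled PKI.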
